A study of Homo sapiens with 9 samples.

How the data were processed

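Total RNA from 9 samples of MDA-MB-231 cells was sequenced by the authors, 3 libraries each for control (scrambled shRNA), shAPT1 (APT1 knockdown) and APT1wt (APT1 overexpression). Per the submitters' processing notes, reads were checked with FastQC, quantified with Salmon on build GRCh38.p10 and analysed with DESeq2, without versions. The deposited Salmon files of each library hold estimated counts (expected counts) and TPM for 199324 transcripts of 58219 genes, with effective lengths. The deposited gene table holds a signal scaled between libraries by the authors; how it was scaled is not stated, and its column sums lie between 14557704 and 15505929. The estimated counts were summed per gene, rounded and used for the tests, TPM summed per gene was used for levels, and the deposited table served as an alternative. Gene positions came from GENCODE 29 on GRCh38, which matched 15157 of the 15200 tested genes by identifier.

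Depth was 12381931 to 18667383 estimated reads per library. Intervals from the fits cover spread between libraries, and counting limits cover counting error only. Bootstrap intervals resample the genes of a fit and do not cover spread between libraries. Genes were kept by edgeR's filterByExpr and scaled by TMM, and all 9 libraries entered a quasi-likelihood fit with the 3 contrasts shAPT1 against control, APT1wt against control and shAPT1 against APT1wt (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05). An exact permutation test of 3 against 3 libraries cannot go below 0.1. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Of 31 gene lists, 29 had at least 5 tested genes and were tested with camera on voom values, with a preset correlation of 0.01 and with an estimated one, and with fry. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

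Genes were named by this rule. LYPLA1 and LYPLA2 were named in every comparison. NUMB, NOTCH1, CTNNB1 and CDC42 were named in both comparisons with control. Among protein-coding genes past 0.05 with a mean TPM of at least 1 in either group and no overlap between the groups, the 8 largest changes each way were eligible, or 5 in the direct comparison of shAPT1 with APT1wt. From each list that passed camera or had at least 3 members past 0.05, and from the Notch and Wnt lists in any case, up to 4 members with the largest changes were eligible. Genes outside the rule are named as chosen after their values were seen.

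Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of at least 20 reads in 3 libraries, an offset for average transcript length, the deposited table, fitting only the groups compared, a block for the replicate number, a test against a change of 1.5-fold, and leaving out each library in turn. Chosen after seeing the data were a correction for gene length and GC content, list counts under each scaling, and a correction that removed from each library the median deviation of the 50 nearest tested genes on each side. Shared controls were assessed with 20 simulations of unchanged groups. The test was tried on data simulated from the means and spread of all 9 libraries, with genes changed in shAPT1. In shAPT1 against control edgeR recovered 22% of genes changed 1.25-fold, 63.3% at 1.5-fold, 79.6% at 2-fold and 91.8% at 4-fold, with 9 false among 135 calls. The meaning of the D1 to D3 marks in the labels is not given, so the reported fit had no block.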

Results

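RNA was sequenced from MDA-MB-231 cells, an established human line derived from a breast carcinoma without hormone receptors. The study concerned APT1, the acyl-protein thioesterase encoded by LYPLA1, which removes palmitate from cysteines of membrane-bound proteins, and how Notch and Wnt signalling are shared out when a cell divides. The 9 libraries formed 3 groups of 3. Control cells carried a scrambled shRNA, shAPT1 cells carried a lentiviral shRNA against APT1, and APT1wt cells carried a lentivirus for overexpression of wild-type APT1. Depth ranged from 12381931 to 18667383 estimated reads per library, and 14134 to 15133 genes had at least 10 reads. The MT-CO1 mRNA was the most abundant gene in each library, with 1.08% to 1.45% of reads. Libraries of a group differed by more than counting noise, with chi-square values per gene of 2.07 to 16.8 over genes with at least 50 reads, as separate preparations of 1 RNA may also do. Each was counted as a separate sample because the labels list it as one. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Log2 fold changes are given ± SE and transcript abundance in TPM, a length-corrected share of a library, as mean ± SD over 3 libraries.

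LYPLA1 (ENSG00000120992.17; chromosome 8, 54046367 to 54102017, minus strand, GRCh38) was measured first in each library. It stood at 87.1, 92.7 and 80.5 TPM in the control libraries, at 38.2, 30.5 and 36.7 TPM in shAPT1, and at 169, 171 and 170 TPM in APT1wt. The knockdown lowered it with a log2 fold change of -1.29 ± 0.07 (adjusted p = 2.0e-08), from 86.8 ± 6.1 to 35.1 ± 4.1 TPM. In APT1wt the fold change on summed reads was 0.60 ± 0.06 (adjusted p = 1.2e-05), and 0.99 (adjusted p = 1.1e-05) once the mean transcript length of each library entered the fit as an offset. The transcript ENST00000316963.7 spans 9 exons and averaged 31.97 ± 4.8 TPM in control, 10.1 ± 2.9 in shAPT1 and 44.4 ± 3.0 in APT1wt (n = 3 each). Not every transcript followed the gene: ENST00000618741.1 averaged 5.75 ± 3.1 TPM in shAPT1 beside 4.79 ± 1.5 in control and was listed at 0 in APT1wt. Of the rise in TPM in APT1wt, most was assigned to ENST00000520718.1, of 577 nt and annotated as a processed transcript, at 66.3 ± 2.5 TPM beside 13.6 ± 4.2 in control. The paralog LYPLA2, or APT2, stood at 39.7 ± 5.3 TPM in control, 36.5 ± 1.8 in shAPT1 and 40.2 ± 4.8 in APT1wt. Its fold change in shAPT1 of -0.26 ± 0.09 (adjusted p = 0.047) did not pass in 17 of 22 other settings.

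**Figure D1:**
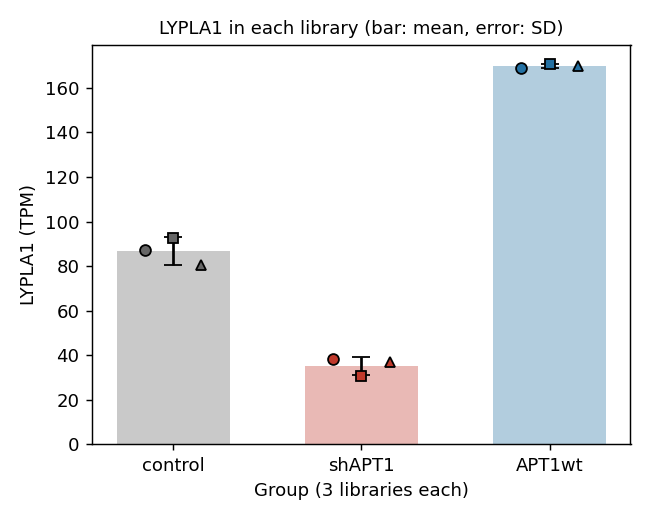
LYPLA1 in TPM for each of the 9 libraries, with 3 libraries in each of the control, shAPT1 and APT1wt groups; bars are group means, error bars are SDs and symbols are single libraries. The 3 groups do not overlap, with means of 86.8 in control, 35.1 in shAPT1 and 170 TPM in APT1wt.

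The comparison of shAPT1 with control asked which genes respond to loss of APT1. The chemokine receptor gene CXCR4 rose from 0.948 ± 0.094 to 17.1 ± 2.4 TPM (log2 fold change 4.13 ± 0.24, adjusted p = 3.5e-08), and ADAMTS1, a secreted metalloprotease gene, from 2.25 ± 0.48 to 30.0 ± 2.5 TPM (4.30 ± 0.14, adjusted p = 2.5e-10). The Wnt antagonist gene DKK1 rose from 185 ± 3.4 to 584 ± 48 TPM (1.61 ± 0.06, adjusted p = 1.1e-09). Genes that were nearly silent in control also rose, among them AMPH (5.46 ± 0.38), LYPD6B (5.34 ± 0.29), PLXDC2 (4.87 ± 0.39), OLR1 (4.85 ± 0.56), the muscarinic receptor gene CHRM3 (4.83 ± 0.40) and NAP1L3 (4.81 ± 0.49), with adjusted p of at most 2.6e-05. Cytokine genes fell: CSF3, which encodes G-CSF, went from 36.5 ± 3.3 to 2.90 ± 2.4 TPM (-3.94 ± 0.28, adjusted p = 2.6e-07). TNIP3 (-2.73 ± 0.35, adjusted p = 6.4e-05), ASB2 (-2.53 ± 0.14, adjusted p = 2.1e-08) and CHST4 (-2.26 ± 0.26, adjusted p = 2.9e-05) also fell.

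Of the 24 tested genes in the list of NF-kappaB and cytokine genes, 15 fell and 9 did not pass in shAPT1 (camera, adjusted p = 1.1e-10; adjusted p = 0.50 with an estimated correlation). With p adjusted over the list alone, 1 rose and 17 fell. Beside CSF3, the list held CSF2, which encodes GM-CSF (-2.15 ± 0.33, adjusted p = 3.0e-04), and the chemokine genes CXCL3 (-2.03 ± 0.34, adjusted p = 6.2e-04) and CXCL2 (-2.01 ± 0.35, adjusted p = 8.1e-04). The shAPT1 libraries were not alike for these genes. IL6, CXCL8 and CXCL1, chosen after their values were seen, stood at 46.8, 138 and 143 TPM in shAPT1 replicate 1, beside control means of 41.5 ± 3.5, 157 ± 18 and 137 ± 23 TPM. In shAPT1 replicates 2 and 3, IL6 stood at 10.0 and 10.7 TPM, CXCL8 at 22.6 and 22.8, and CXCL1 at 16.63 and 15.03. CXCR4 did not follow that split, with 14.3, 18.7 and 18.2 TPM in the 3 shAPT1 libraries. Without shAPT1 replicate 1, 21 of the 24 genes fell.

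**Figure D2:**
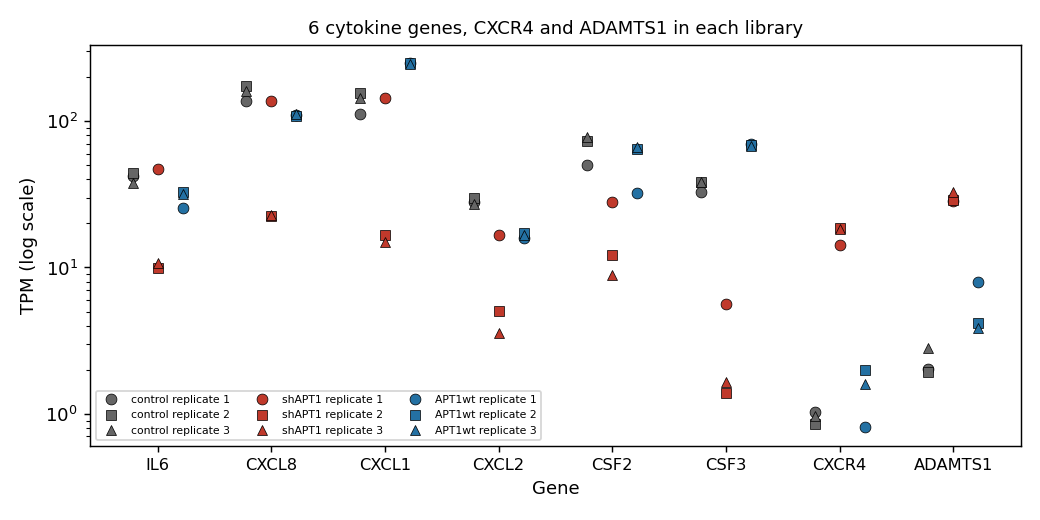
TPM on a log scale of 6 cytokine genes, CXCR4 and ADAMTS1 in each library; colours are the 3 groups and symbols the replicate numbers. For IL6, CXCL8 and CXCL1, shAPT1 replicate 1 lies near the control libraries and replicates 2 and 3 lie below them, while CXCR4 and ADAMTS1 lie above control in all 3 shAPT1 libraries.

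Cytosolic ribosomal protein genes fell as a group in shAPT1: 42 of 82 fell, 1 rose and 39 did not pass, with a median log2 fold change of -0.20 (camera, adjusted p = 3.2e-12; adjusted p = 0.50 with an estimated correlation). The counts adjusted over the list alone were 2 higher and 57 lower. Reads of genes with symbols of RPL or RPS and a number, a set that leaves out list members such as RPLP1, were also summed. They made up 3.84% to 4.04% of each shAPT1 library and 4.325% to 4.601% of each control library. RPL10 (-0.46 ± 0.07, adjusted p = 3.2e-04), RPL36 (-0.46 ± 0.08, adjusted p = 6.0e-04) and RPS15 (-0.44 ± 0.08, adjusted p = 0.0011) were among the list members that fell. After a correction for the change of neighbouring genes on the chromosome, their fold changes were -0.30, -0.29 and -0.19, all still past the threshold. Genes for nuclear-encoded respiratory chain subunits also leaned lower, with 14 lower and 2 higher of 72, the same counts adjusted over the list alone (camera, adjusted p = 0.037; adjusted p = 0.76 with an estimated correlation). ATP5G1 (-0.51 ± 0.06, adjusted p = 4.9e-05), NDUFA8 (-0.51 ± 0.07, adjusted p = 2.0e-04) and NDUFB2 (-0.41 ± 0.07, adjusted p = 5.0e-04) fell. This list did not pass without control replicate 1 (adjusted p = 0.24), without shAPT1 replicate 1 (adjusted p = 0.060), with no filter on low counts (adjusted p = 0.051) or by fry (adjusted p = 0.12).

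Another 3 lists rose in shAPT1. Among 14 tested markers of stem-like and tumour-initiating breast cells, 8 rose and 1 fell, the same counts adjusted over the list alone (camera, adjusted p = 0.019; adjusted p = 0.27 with an estimated correlation). Beside CXCR4, CD24 rose (2.01 ± 0.25, adjusted p = 5.6e-05), as did the integrin gene ITGB3 (1.46 ± 0.22, adjusted p = 3.3e-04), while CD44 fell (-0.66 ± 0.08, adjusted p = 2.7e-05; -0.42 with the transcript length offset and in the deposited table). A high CD44 and low CD24 level is the usual mark of stem-like breast cancer cells, so CD24 and CD44 moved against the name of the list. Among 22 targets of the YAP and TAZ coactivators, 11 rose and 4 fell, again the same counts adjusted over the list alone (camera, adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation). TGFB2 (1.14 ± 0.10, adjusted p = 2.0e-06), ANKRD1 (0.96 ± 0.12, adjusted p = 6.4e-05) and F3, the tissue factor gene (0.84 ± 0.06, adjusted p = 2.7e-07), rose. Of 35 type I interferon response genes 8 rose and 27 did not pass, also when adjusted over the list alone (camera, adjusted p = 0.046; adjusted p = 0.76 with an estimated correlation). The interferon list did not pass without control replicate 2 (adjusted p = 0.070), control replicate 3 (adjusted p = 0.19) or shAPT1 replicate 1 (adjusted p = 0.29), nor by fry (adjusted p = 0.17).

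The Notch and Wnt lists, central to the question, moved in both directions in shAPT1. Of 35 Notch pathway components 6 rose and 4 fell (camera, adjusted p = 0.96), and of 19 Notch targets 2 rose and 4 fell (camera, adjusted p = 0.38). Adjusted over the list alone, 7 components rose and 4 fell, and 2 targets rose and 4 fell. The ligand gene JAG1 rose from 10.1 ± 0.28 to 21.9 ± 1.6 TPM (1.05 ± 0.08, adjusted p = 8.7e-07). The receptor gene NOTCH1 fell from 20.2 ± 1.8 to 12.4 ± 0.99 TPM (-0.76 ± 0.07, adjusted p = 5.9e-06; -0.41 after the correction for neighbouring genes), as did LFNG, which encodes a glycosyltransferase that modifies Notch (-0.95 ± 0.15, adjusted p = 4.8e-04). NUMB, which encodes a Notch inhibitor inherited unequally in asymmetric divisions, stood at 55.3 ± 1.6 TPM beside 47.5 ± 1.3 in control (0.17 ± 0.06, adjusted p = 0.050) and did not pass. Of 39 Wnt pathway components 6 rose and 7 fell (camera, adjusted p = 0.53), and of 26 Wnt/beta-catenin targets 5 rose and 5 fell (camera, adjusted p = 0.89). Adjusted over the list alone, 7 components rose and 8 fell, and 6 targets rose and 5 fell. WNT5A rose from 0.0834 ± 0.008 to 1.24 ± 0.21 TPM (4.12 ± 0.36, adjusted p = 2.0e-06) and WNT7B fell from 7.40 ± 1.97 to 3.36 ± 0.22 TPM (adjusted p = 3.6e-05). Of the targets, RNF43, which encodes a ubiquitin ligase for Frizzled receptors, rose (2.50 ± 0.24, adjusted p = 4.5e-06) and PLAUR fell (-0.72 ± 0.07, adjusted p = 3.6e-06). The beta-catenin gene CTNNB1 (0.08 ± 0.06, adjusted p = 0.32) and CDC42 (-0.05 ± 0.06, adjusted p = 0.60) did not pass. Of 33 genes for cell polarity and asymmetric division 6 rose and 2 fell (camera, adjusted p = 0.39), and 7 rose and 2 fell adjusted over the list alone.

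In all, 3711 of 15200 tested genes differed between shAPT1 and control by edgeR's quasi-likelihood test, 1946 higher and 1765 lower, and 565 of them by at least 2-fold. Scaling by the library total alone gave 2224 higher and 1481 lower, and the correction for gene length and GC content turned the balance to 1876 higher and 2451 lower. The groups were fully separate for 31.1% of the tested genes, where chance alone gives 10%. With the transcript length offset, 2307 genes differed. Of the markers of other cell types, LCP1 rose (1.94 ± 0.09) and HLA-DRA (-1.65 ± 0.09) and CD74 (-1.11 ± 0.10) fell among 7 tested leukocyte markers, of which 1 rose and 4 fell (camera, adjusted p = 0.26). Of 4 tested fibroblast markers, too few for camera, COL1A2 (1.69 ± 0.35), PDGFRB (1.39 ± 0.21) and COL1A1 (0.51 ± 0.13) rose and FBLN1 fell (-1.14 ± 0.15), the same adjusted over the list alone. Of 5 endothelial markers 2 rose (camera, adjusted p = 0.30), TIE1 and ESAM, also adjusted over the list alone; these were chosen after their values were seen.

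The comparison of APT1wt with control asked which genes respond to extra APT1. The controls carried a scrambled shRNA, and no group carried an empty overexpression vector. Effects of extra APT1 therefore cannot be told apart from effects of the different vectors. Genes of the extracellular matrix and its proteases were mostly higher: of 30 tested, 17 rose, 7 fell and 6 did not pass, the same counts adjusted over the list alone (camera, adjusted p = 0.0030; adjusted p = 0.83 with an estimated correlation). COL7A1, which encodes the collagen of anchoring fibrils, rose from 52.8 ± 1.7 to 150 ± 16 TPM (1.58 ± 0.06, adjusted p = 3.1e-09), and MMP9 (1.80 ± 0.24, adjusted p = 1.1e-04) and TIMP3 (1.53 ± 0.15, adjusted p = 4.7e-06), the genes of a metalloprotease and of a metalloprotease inhibitor, rose with it. Of 18 mesenchymal markers 9 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.016; adjusted p = 0.79 with an estimated correlation), among them CDH11 (1.45 ± 0.08, adjusted p = 4.7e-08), TAGLN (1.09 ± 0.10, adjusted p = 2.6e-06) and FN1 (1.08 ± 0.14, adjusted p = 6.0e-05). CDH11 (2.17 ± 0.08), TAGLN (1.51 ± 0.10) and FN1 (1.18 ± 0.14) rose in shAPT1 as well, with adjusted p of at most 3.1e-05, but the mesenchymal list did not pass there, with 6 of 18 higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.059; adjusted p = 0.50 with an estimated correlation). By fry the mesenchymal list passed in both lines (adjusted p = 0.0015 in shAPT1 and 0.0026 in APT1wt). In shAPT1 against APT1wt 5 of 18 mesenchymal markers were higher and 4 lower, or 5 and 5 adjusted over the list alone. The list did not pass there (camera, adjusted p = 0.80), so it showed no common direction between the lines, though single members differed. Of the 4 fibroblast markers 2 rose in APT1wt, also adjusted over the list alone: PDGFRB (1.14 ± 0.21, adjusted p = 0.0015) and COL1A1 (0.54 ± 0.13, adjusted p = 0.0077), both chosen after their values were seen. Interferon response genes leaned the other way, with 14 of 35 lower and 4 higher, also adjusted over the list alone (camera, adjusted p = 0.016; adjusted p = 0.83 with an estimated correlation; fry, adjusted p = 0.14).

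Among single genes, FAM65C rose from 3.23 ± 0.37 to 35.5 ± 5.0 TPM (3.46 ± 0.17, adjusted p = 1.5e-08), and the growth factor gene IGF2 from 0.642 ± 0.24 to 5.87 ± 1.6 TPM (3.41 ± 0.26, adjusted p = 4.9e-07). The potassium channel gene KCNN3 (3.33 ± 0.24), OLFML3 (3.38 ± 0.29) and IGFN1 (3.18 ± 0.16) rose with adjusted p of at most 1.5e-06. GLB1L2 fell from 1.88 ± 0.63 to 0.0155 ± 0.014 TPM (-5.86 ± 0.52, adjusted p = 2.4e-06). The cancer-testis genes MAGEC2 (-5.28 ± 0.44) and PAGE5 (-4.94 ± 0.41), TRIML2 (-3.08 ± 0.31) and DMBT1 (-2.56 ± 0.26) fell with adjusted p of at most 9.1e-06. IFI44 (-1.74 ± 0.20, adjusted p = 2.4e-05), OASL (-1.57 ± 0.31, adjusted p = 0.0022) and the RNA helicase gene DDX60 (-1.46 ± 0.15, adjusted p = 9.1e-06) were among the interferon response genes that fell.

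Some metabolic and cell cycle lists rose by smaller steps in APT1wt, while others did not pass: 5 genes were higher and 7 lower of 34 for G1/S and DNA replication (camera, adjusted p = 0.79), 5 and 4 of 23 for fatty acid synthesis (camera, adjusted p = 0.64) and 9 and 8 of 72 for the respiratory chain (camera, adjusted p = 0.74). These were 5 and 7, 6 and 4, and 9 and 8 adjusted over the list alone. Of 29 hypoxia and glycolysis genes 9 rose and 2 fell (camera, adjusted p = 0.0099; adjusted p = 0.79 with an estimated correlation), and adjusted over the list alone 10 rose and 2 fell. PFKFB4, a regulator of glycolytic flux (1.42 ± 0.12, adjusted p = 1.9e-06), and ADM, which encodes adrenomedullin (0.84 ± 0.07, adjusted p = 9.3e-07), were among them. Of 31 G2/M genes 9 rose and 1 fell (camera, adjusted p = 0.011; adjusted p = 0.83 with an estimated correlation), or 10 and 1 adjusted over the list alone, with KIF20A (0.48 ± 0.06, adjusted p = 7.7e-05) and DLGAP5 (0.43 ± 0.06, adjusted p = 2.3e-04) as examples. Of 25 cholesterol biosynthesis genes 9 rose and 2 fell (camera, adjusted p = 0.044; adjusted p = 0.79 with an estimated correlation), or 10 and 2 adjusted over the list alone. The cholesterol list did not pass without control replicate 3 (adjusted p = 0.080) or APT1wt replicate 1 (adjusted p = 0.11). Of 82 ribosomal protein genes 14 rose and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.025; adjusted p = 0.87 with an estimated correlation). That list did not pass by fry (adjusted p = 0.29) or without control replicate 2 (adjusted p = 0.17), control replicate 3 (adjusted p = 0.080), APT1wt replicate 1 (adjusted p = 0.083) or APT1wt replicate 3 (adjusted p = 0.093).

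The Notch and Wnt lists did not pass in APT1wt either. Of 35 Notch components 4 rose and 4 fell (camera, adjusted p = 0.81), and of 19 Notch targets 6 rose and 2 fell (camera, adjusted p = 0.79). NOTCH2 rose (0.48 ± 0.08, adjusted p = 3.7e-04) and TNC, a Notch target that encodes tenascin C, fell (-0.67 ± 0.08, adjusted p = 3.7e-05). NOTCH1 was lower (-0.31 ± 0.07, adjusted p = 0.0073), but at -0.10 (adjusted p = 0.36) after the correction for neighbouring genes it no longer passed. NUMB rose from 47.5 ± 1.3 to 54.6 ± 3.3 TPM (0.24 ± 0.06, adjusted p = 0.0095), a call lost with the length offset (adjusted p = 0.10) and without control replicate 3 (adjusted p = 0.063). Of 39 Wnt components 4 rose and 3 fell (camera, adjusted p = 0.87), and of 26 Wnt/beta-catenin targets 8 rose and 1 fell (camera, adjusted p = 0.38). The ligand gene WNT10A rose (1.84 ± 0.26, adjusted p = 1.3e-04), as did CTNNB1 (0.32 ± 0.06, adjusted p = 8.8e-04) and RNF43 (1.38 ± 0.26, adjusted p = 0.0015). The receptor gene FZD1 fell (-0.58 ± 0.08, adjusted p = 1.4e-04; -0.31 after the correction for neighbouring genes). Of 33 polarity genes 9 rose and 4 fell (camera, adjusted p = 0.13), with PRKCZ, which encodes an atypical protein kinase C (10.5 ± 2.3 TPM beside 5.40 ± 2.6 in control, adjusted p = 9.8e-04), and LLGL2 (1.07 ± 0.19, adjusted p = 0.0011) higher. Adjusted over the list alone, 4 and 4 Notch components, 6 and 3 Notch targets, 4 and 3 Wnt components, 8 and 1 Wnt targets and 11 and 4 polarity genes rose and fell. CDC42 did not pass (0.13 ± 0.06, adjusted p = 0.18). In all, 3567 genes differed, 1793 higher and 1774 lower, and 589 by at least 2-fold. Scaling by the library total alone gave 1487 higher and 2053 lower. The groups were fully separate for 35.05% of genes, where chance gives 10%. With the length offset 2228 genes differed, and without APT1wt replicate 3, 2298. LCP1 (2.56 ± 0.09), HLA-DRA (-1.75 ± 0.10) and CD74 (-0.87 ± 0.10) changed here as in shAPT1.

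**Figure D3:**
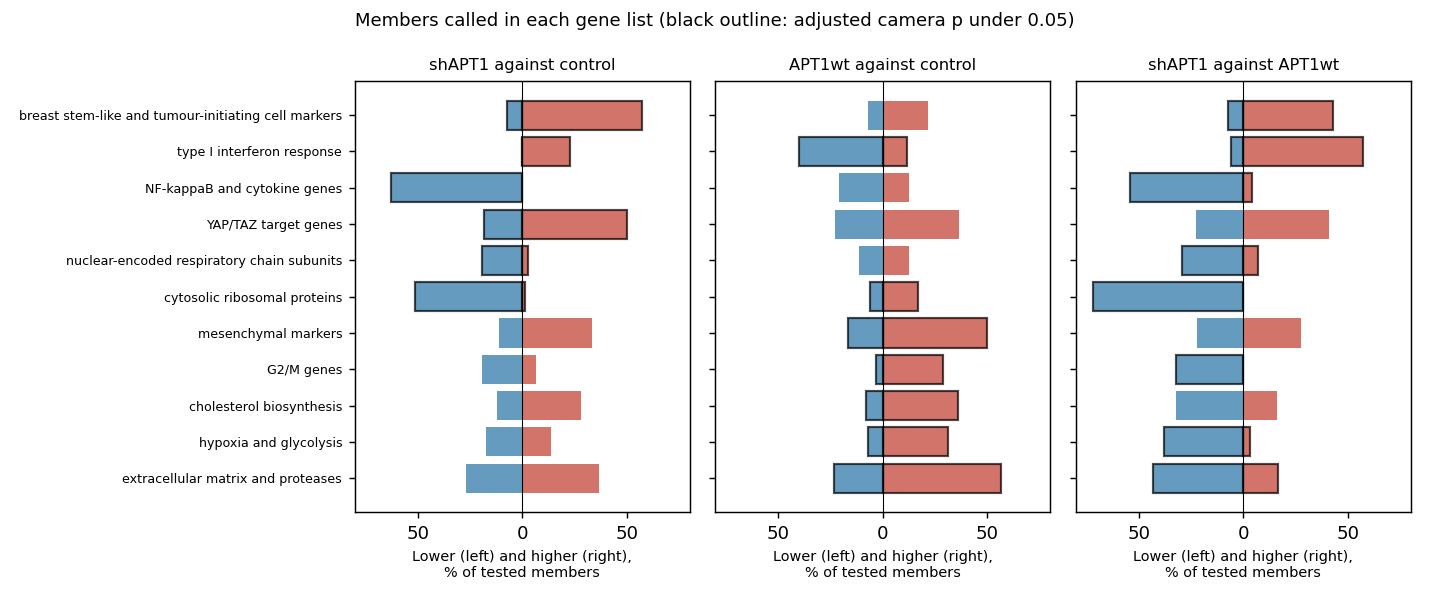
Share of tested members called higher (right, red) and lower (left, blue), in percent, for the 11 gene lists that passed camera in at least 1 comparison; black outlines mark an adjusted camera p under 0.05 with a preset correlation of 0.01. The NF-kappaB and ribosomal protein lists lie mostly to the left for shAPT1 against control, with 15 of 24 and 42 of 82 members lower.

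Genes also moved together by chromosome, a comparison made after the values were seen. In APT1wt, 202 of the 269 tested genes of chromosome 13 were higher and 1 was lower than in control, with a median log2 fold change of 0.66. Of 482 tested genes on the X chromosome 270 were lower and 5 higher (median -0.37), and of 755 on chromosome 7, 273 were lower and 23 higher (median -0.25). The last 5 windows of 20 Mb on chromosome 4, from 100000001 to the end, had medians between -0.27 and -0.36. In shAPT1, 140 of the chromosome 13 genes were higher and 4 lower (median 0.30), 87 of 228 on chromosome 18 were higher and 9 lower (median 0.23), and 163 on chromosome 7 were lower and 45 higher (median -0.145). Of 243 genes on chromosome 9 between 120000001 and 140000000, the window that holds NOTCH1, 111 were lower and 5 higher in shAPT1 (median -0.28), and 85 lower and 12 higher in APT1wt (median -0.20). The 3 APT1wt libraries gave chromosome 13 medians of 0.65 to 0.67, the 3 shAPT1 libraries 0.24 to 0.40 and the controls -0.01 to 0.02, each relative to the control mean. With the change of the 50 nearest tested genes on each side removed, 3176 genes differed in shAPT1 and 2353 in APT1wt. ZDHHC20, a palmitoyltransferase gene on chromosome 13, was higher in APT1wt (1.06 ± 0.08, adjusted p = 3.7e-07) and had a corrected fold change of 0.17 that did not pass. LYPLA1 kept a corrected value of 0.56 in APT1wt.

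**Figure D4:**
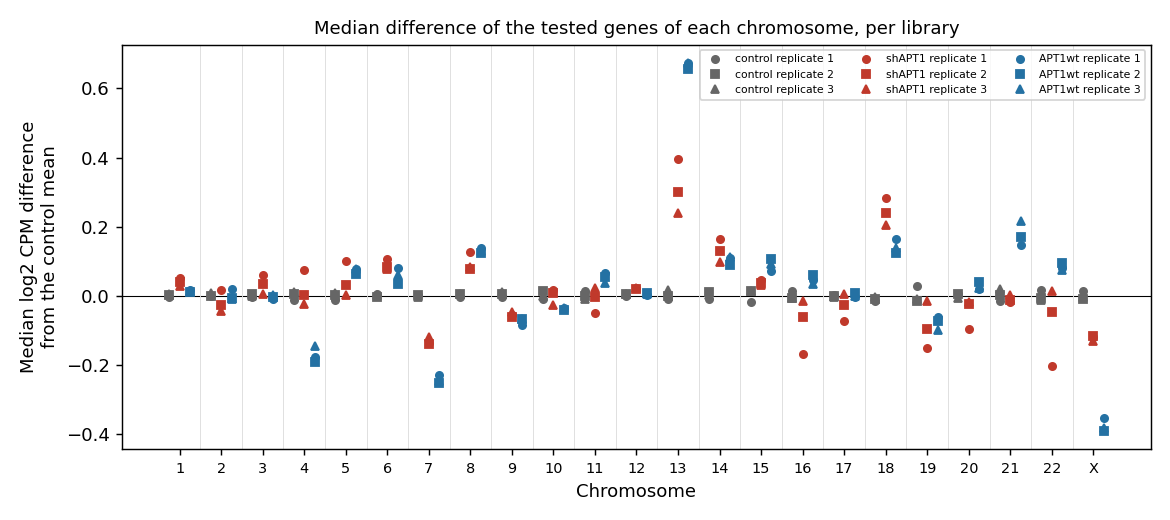
Median log2 CPM difference from the mean of the control libraries over the tested genes of each chromosome, for each of the 9 libraries; colours are the 3 groups and symbols the replicate numbers. The APT1wt libraries lie between 0.65 and 0.67 on chromosome 13 and between -0.39 and -0.35 on the X chromosome.

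The direct comparison of shAPT1 with APT1wt asked how the low and the high APT1 level differ. Here too the vectors differed, an shRNA in shAPT1 and an overexpression lentivirus in APT1wt, so the APT1 level was not the only difference. Of 35 interferon response genes 20 were higher in shAPT1 than in APT1wt, 2 were lower and 13 did not pass (camera, adjusted p = 1.4e-06; adjusted p = 0.50 with an estimated correlation). The count was 21 higher and 2 lower adjusted over the list alone. IFIT1 stood at 27.3 ± 13 TPM in shAPT1 and 7.42 ± 2.2 in APT1wt (1.71 ± 0.30, adjusted p = 8.2e-04), IFIT2 at 18.5 ± 8.9 and 4.62 ± 0.93 (1.88 ± 0.25, adjusted p = 9.9e-05), and OASL was also higher (1.55 ± 0.31, adjusted p = 0.0022). Replicate 1 had the most IFIT1 in every group, at 24.4 TPM in control, 42.0 in shAPT1 and 9.97 in APT1wt. Replicates 2 and 3 had 15.2 and 13.9, 19.2 and 20.7, and 5.94 and 6.36 TPM. ISG15, chosen after its values were seen, was also highest in replicate 1 of every group, while MX1, chosen likewise, was so only in control. For IFIT1 and ISG15, part of the spread thus went with the replicate number. Over all tested genes it hardly did: deviations from the group mean correlated at -0.055 to 0.103 between libraries of the same number. Of the 9 libraries, 5 correlated best with one of their own number. Ribosomal protein genes were lower in shAPT1 for 59 of 82, or 65 lower and 1 higher adjusted over the list alone, with a median of -0.26 (camera, adjusted p = 1.3e-19; adjusted p = 0.50 with an estimated correlation). RPLP1 is an example (-0.49 ± 0.08, adjusted p = 3.6e-04). NF-kappaB and cytokine genes were lower for 13 of 24 and higher for 1, or 14 and 1 adjusted over the list alone (camera, adjusted p = 2.4e-07; adjusted p = 0.52 with an estimated correlation). CSF3 stood at 2.90 ± 2.4 TPM in shAPT1 and 68.7 ± 1.4 in APT1wt (-4.83 ± 0.27, adjusted p = 2.5e-08) and IL1B was lower (-2.05 ± 0.29, adjusted p = 1.7e-04), with shAPT1 replicate 1 again nearer the other groups for IL6, CXCL8 and CXCL1.

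Of 31 G2/M genes 10 were lower in shAPT1 than in APT1wt and 21 did not pass, or 13 lower adjusted over the list alone (camera, adjusted p = 1.2e-04; adjusted p = 0.50 with an estimated correlation). The mitotic kinase gene PLK1 (-0.72 ± 0.07, adjusted p = 5.7e-06) and the cyclin gene CCNB1 (-0.42 ± 0.05, adjusted p = 7.1e-05) were among them. Hypoxia and glycolysis genes were lower for 11 and higher for 1 of 29, or 12 and 2 adjusted over the list alone (camera, adjusted p = 0.0021; adjusted p = 0.50 with an estimated correlation), with PFKFB4 at -1.18 ± 0.12 (adjusted p = 8.6e-06) and VEGFA at -0.63 ± 0.07 (adjusted p = 2.5e-05). Respiratory chain genes were lower for 21 and higher for 5 of 72, also adjusted over the list alone (camera, adjusted p = 0.0029; adjusted p = 0.60 with an estimated correlation). Matrix genes were lower for 13 and higher for 5 of 30, or 15 and 5 adjusted over the list alone (camera, adjusted p = 0.030; adjusted p = 0.61 with an estimated correlation), led by COL7A1 (-1.85 ± 0.06, adjusted p = 5.0e-10), LAMA5 (-1.23 ± 0.12, adjusted p = 6.9e-06) and MMP9 (-2.11 ± 0.25, adjusted p = 3.3e-05). The matrix list did not pass without control replicate 1 (adjusted p = 0.057), without shAPT1 replicate 1 (adjusted p = 0.18) or after the correction for neighbouring genes (adjusted p = 0.18). Stem-like markers were higher for 6 and lower for 1 of 14, also adjusted over the list alone (camera, adjusted p = 0.025; adjusted p = 0.50 with an estimated correlation), CXCR4 among them (3.53 ± 0.21, adjusted p = 6.0e-08). That list did not pass without control replicate 1 (adjusted p = 0.061), control replicate 2 (adjusted p = 0.053) or shAPT1 replicate 1 (adjusted p = 0.062).

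Notch targets were lower for 6 and higher for 1 of 19 in shAPT1 against APT1wt (camera, adjusted p = 0.093; adjusted p = 0.53 with an estimated correlation), or 7 and 1 adjusted over the list alone, and the list passed by fry (adjusted p = 0.044) and with no filter on low counts (adjusted p = 0.015). LFNG (-1.50 ± 0.15, adjusted p = 6.7e-06) and the Notch target NRARP (-1.22 ± 0.22, adjusted p = 0.0010) were lower, and JAG1 was higher (1.27 ± 0.08, adjusted p = 1.4e-07). Of 26 Wnt targets 7 were higher and 9 lower (camera, adjusted p = 0.61), and of 39 Wnt components 7 were higher and 11 lower (camera, adjusted p = 0.33), with DKK1 (1.29 ± 0.06, adjusted p = 5.8e-09) and WNT5A (6.08 ± 0.44, adjusted p = 4.2e-07) higher and WNT10A lower (-1.73 ± 0.25, adjusted p = 1.7e-04). Of 35 Notch components 5 were higher and 6 lower (camera, adjusted p = 0.77), and of 33 polarity genes 3 were higher and 8 lower (camera, adjusted p = 0.42). Adjusted over the list alone, the higher and lower genes were 8 and 9 Wnt targets, 7 and 13 Wnt components, 6 and 7 Notch components and 3 and 10 polarity genes. KBTBD8 (7.01 ± 0.48), PDE1C (6.53 ± 0.34) and NRK (6.50 ± 0.31) were higher, and KCNN3 (-4.51 ± 0.27), ENG (-3.95 ± 0.17) and IGFN1 (-3.69 ± 0.17) lower, with adjusted p of at most 2.0e-07. MSI2, which encodes an RNA-binding protein that represses NUMB translation, was higher (4.05 ± 0.18, adjusted p = 3.3e-09; 2.15 with the length offset). In all, 3833 genes differed, 1942 higher and 1891 lower, while scaling by the library total alone gave 2632 higher and 1330 lower and the length and GC correction 2031 higher and 2735 lower. The groups were fully separate for 32.9% of genes, where chance gives 10%, and 2374 genes differed with the length offset.

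The enzymes that add or remove palmitate, the class APT1 belongs to, changed in both directions. Of 29 tested, 7 rose and 5 fell in shAPT1 (camera, adjusted p = 0.53), 5 rose and 4 fell in APT1wt (camera, adjusted p = 0.79), and 3 were higher and 3 lower in shAPT1 than in APT1wt (camera, adjusted p = 0.61). By fry the list passed as higher in shAPT1 (adjusted p = 0.0015) and APT1wt (adjusted p = 5.2e-05), and as lower in their direct comparison (adjusted p = 0.0051). In that direct comparison the list's median log2 fold change was 0.095, its mean was -0.015 and camera's direction was higher. LYPLA1, whose level was set by design, belongs to this class and was not left out, so fry does not tell the other enzymes from it. Adjusted over the list alone, these were 7 and 6, 6 and 4, and 3 and 3. Of 33 RAS family and other palmitoylated signalling proteins, 6 rose and 8 fell in shAPT1 (camera, adjusted p = 0.69) and 4 rose and 3 fell in APT1wt (camera, adjusted p = 0.74), or 7 and 9 and 4 and 3 adjusted over the list alone. With an estimated correlation camera passed 0 of the 29 lists in each comparison, with 2, 0 and 1 lists at an unadjusted p under 0.05 for shAPT1, APT1wt and their direct comparison, while fry, which tests a list without comparing it with other genes, passed 9, 8 and 15.

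The lines were also compared through their changes against the shared control. Of the 1625 genes called in both, 833 rose in both and 651 fell in both, where independent lists would share 230 and 206. Another 80 rose in shAPT1 and fell in APT1wt, and 61 did the reverse, where independent lists would share 227 and 208. The 1625 shared calls were 1034 without control replicate 3, 1058 without control replicate 2, 896 with the length offset, 887 in the deposited table, 1074 after the correction for neighbouring genes and 112 against a change of 1.5-fold. The 141 with opposite directions were 75, 64 and 69 without control replicates 1, 2 and 3, 213 and 93 without shAPT1 replicates 1 and 2, and 79 and 81 without APT1wt replicates 2 and 3. They were 46 with the length offset, 43 in the deposited table, 4 against 1.5-fold and 248 after the length and GC correction. Across all alternatives, 89.1% to 96.4% of the shared calls had the same direction. CDH11, TAGLN, FN1, TIMP3, RNF43 and LCP1 rose in both, and HLA-DRA, CD74, TNC and FZD1 fell in both. LFNG, CSF3 and EGR1 differed in direction: LFNG was lower in shAPT1 and higher in APT1wt (0.55 ± 0.14, adjusted p = 0.0096; adjusted p = 0.054 without APT1wt replicate 2), and CSF3 likewise (0.89 ± 0.19, adjusted p = 0.0035; adjusted p = 0.24 by DESeq2). The immediate early gene EGR1 rose in shAPT1 (1.06 ± 0.16, adjusted p = 3.1e-04) and fell in APT1wt (-0.95 ± 0.19, adjusted p = 0.0027). Across 15200 genes, which are not independent replicates, the fold changes correlated at 0.41, while unchanged groups simulated against the same controls correlated at 0.53 (0.49 to 0.58 over 20 simulations) with 0.1 genes called in both on average. No gene was changed in the simulations, so that count does not measure the overlap that shared controls add among changed genes. The observed covariance was 0.105 beside 0.031 simulated, a difference of 0.074. Signs were the same for 66.7% of genes, beside 67.1% simulated. The 3 control libraries cannot be split into parts of 2, so part of the excess overlap may come from the shared controls.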

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

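The tests in this part were chosen only after the results were seen, except the splits of the libraries. Levels of single LYPLA1 transcripts, which the gene comparisons use only as a sum, showed 2 transcripts at least 2-fold above every control library in all 3 APT1wt libraries. ENST00000520718.1, of 577 nt, averaged 66.34 ± 2.51 TPM in APT1wt and 13.6 ± 4.2 TPM in control (SD, n = 3). ENST00000521352.5, of 580 nt, averaged 13.62 ± 3.32 TPM in APT1wt and was listed at 0 in all 6 other libraries. Others were lower in APT1wt: ENST00000618741.1 was listed at 0 beside 4.79 ± 1.5 TPM in control, and ENST00000519272.5 averaged 4.11 beside 12.4 TPM. The split of reads between ENST00000618741.1 and ENST00000316963.7, which differ mainly in their first exon, is uncertain. ENST00000520718.1 is annotated as a processed transcript and not as protein-coding. These values do not tell reads of the introduced APT1 from reads of the cells' own gene, so they do not show that a transcript of that gene rose. No test was run on what gives rise to these reads.

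NF-kappaB and cytokine genes such as IL6 and CXCL8 were reduced less in shAPT1 replicate 1 than in replicates 2 and 3. Control cells or a wrong label would pull other genes toward control as well, but over 41 genes outside the list that changed at least 4-fold, replicate 1 lay at a median position of 0.902 between control at 0 and the other replicates at 1, with 0.915 for the 29 higher and 0.729 for the 12 lower genes. The 10 genes of the list that changed at least 2-fold lay at 0.418, so control cells are argued against as the whole cause, while a smaller share of them stays open. Replicates 2 and 3 thinned to the reads of replicate 1 kept a median log2 ratio of -0.866 where replicate 1 had -0.37. Random thinning leaves the expected share of each gene unchanged, so this outcome was largely fixed. It shows only that a random loss of reads does not move the median, and it decides nothing further about depth. Replicate 1 also stood apart outside the list. Its chromosome 22 median lay at -0.20 from the control mean, beside -0.05 and 0.01 in replicates 2 and 3, and that of chromosome 16 at -0.17, beside -0.06 and -0.01. Its chi-square values per gene were 11.4 and 16.8 against replicates 2 and 3, which gave 6.86 against each other. A difference in the state of that sample or in the preparation of its library stays open and was not tested.

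Ribosomal protein genes were lower in shAPT1, with a median log2 fold change of -0.20. After a correction for gene length and GC content the median was -0.136 (bootstrap interval over genes -0.178 to -0.110), which argues against that trend as the whole cause, though the change became smaller. That interval treats the genes as independent and leaves out the spread between libraries. Reads shared with annotated pseudogenes named after these genes are argued against. Such pseudogenes held only 1.09% of the combined reads, so their sum with the genes could move little, and it gave a median of -0.203. A response of these genes to the knockdown may remain, as a hypothesis found and tested on the same data, and the list did not pass with an estimated correlation (adjusted p = 0.50).

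Genes of whole chromosomes moved together, such as those of chromosome 13 in both lines. Chance scatter is argued against: the SD of the chromosome medians was 0.187 in APT1wt, where the highest of 1000 shuffles of gene positions gave 0.0246. Gene length and GC content are argued against for chromosome 13 in APT1wt, whose median was 0.666 after that correction, and in shAPT1 only as the whole cause, since the median went from 0.30 to 0.231 (bootstrap interval over genes 0.188 to 0.248). That interval leaves out the spread between shAPT1 libraries, which ran from 0.24 to 0.40 before the correction. A candidate explanation is a difference in copy number between the lines, which would move weakly and strongly expressed genes alike. The medians of the less and the more expressed genes of chromosome 13 were 0.59 and 0.69, a difference of 0.096, and without DNA data this stays a hypothesis that also leaves open how many of the changes stem from APT1.

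Each comparison had 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. The real split called 3711 genes in shAPT1 against control, 3567 in APT1wt against control and 3833 in shAPT1 against APT1wt by edgeR, the highest of the other splits called 1 in each, and 1 of the 10 splits reached the real count.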

How the results depend on the processing

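The length and GC correction and the neighbouring-gene correction were chosen only after the data were seen. Over the alternatives, named genes other than LYPLA1 kept their direction and side of the threshold in 6920 cases, lost the call in 760, gained it in 7 and turned in 5; lists kept theirs in 493, lost it in 43 and gained it in 4. The 5 that turned were in APT1wt under the neighbouring-gene correction: PORCN at 0.042, LATS2 at -0.14, FOSL2 at 0.0075, RAP2A at -0.029 and NDUFB11 at 0.071, where the correction removes the shift of their region. In the order shAPT1, APT1wt and their direct comparison, the transcript length offset called 2307, 2228 and 2374 genes, the gene values deposited by the authors gave 2326, 2237 and 2366, and the test against 1.5-fold, which asks for a larger change, 384, 363 and 357. The neighbouring-gene correction called 2353 in APT1wt. Lists passing were 0, 0 and 0 by camera with an estimated correlation, where 2, 0 and 1 had an unadjusted p under 0.05 and fry passed 9, 8 and 15; with no filter on low counts 12 passed in APT1wt. LYPLA1 in APT1wt stayed at 0.60 but did not pass against 1.5-fold (adjusted p = 1). The correlation of both effects was 0.549 over genes of at least 5 TPM. Apart from the test against 1.5-fold and the neighbouring-gene correction, the cause was not tested. A block for the replicate number called 3757, 3625 and 3871 genes. Leaving out each library gave 2616 to 4096 genes in shAPT1, 2298 (without APT1wt replicate 3) to 4824 in APT1wt and 2573 to 4104 in the direct comparison, with 5 to 7, 5 to 7 and 6 to 8 lists, LYPLA1 at -1.33 to -1.25, 0.56 to 0.64 and -1.91 to -1.86, and a correlation of 0.456 to 0.493 without each control. Depth and 3 libraries per group limit small changes: on simulated data 63.3% of 1.5-fold changes were recovered.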

Other observations

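The tests in this part were chosen only after the results were seen. Genes of MHC class II, which present peptides to CD4 T cells, were lower in both lines. Their transcriptional activator CIITA fell from 12.7 TPM in control to 3.54 TPM in shAPT1 (log2 fold change -1.81 ± 0.11, adjusted p = 6.2e-08) and to 6.41 TPM in APT1wt (-1.004 ± 0.11, adjusted p = 9.9e-06). HLA-DRB1 (-1.58 and -2.01), HLA-DPA1 (-1.27 and -1.76), HLA-DPB1 (-1.31 and -2.06), HLA-DMA (-0.99 and -1.49) and HLA-DMB (-1.36 and -1.39) fell in shAPT1 and APT1wt. HLA-DQA1 and HLA-DOB did not pass in either line, nor did HLA-DOA in APT1wt. Beyond HLA-DRA and CD74, 8 of 11 tested genes, with CIITA itself counted among them, were lower in both lines, as a joint change of these genes would also give.

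MAGEC2 and PAGE5, cancer-testis genes on the X chromosome, stayed far lower in APT1wt after the correction for neighbouring genes (-4.90, adjusted p = 7.8e-06, and -4.56, adjusted p = 8.2e-06). A joint fall of such families would lower their other members too, but the corrected fold changes of 6 others, with paralogs of the same value counted once, had a median of -0.239 (quartiles -0.48 to -0.15). This argues against a joint fall of at least 2-fold, though some of these genes, such as MAGEC1, had few reads. Fisher's exact test on calls is blind to the size of a change and decides nothing here: it gave p = 1 in APT1wt (5 of 9 family genes beside 270 of 473 other X genes) and p = 2.5e-05 in shAPT1 (9 of 9 beside 142 of 473). In shAPT1, 3 family genes rose, such as MAGEC1 (4.02), and 6 fell, such as MAGEC2 (-1.27), while SPANXA1 and SPANXA2 had the same value and XAGE1A and XAGE1B lost their calls after the correction.

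Genes that follow the APT1 level would move in opposite directions under knockdown and overexpression. Of the genes called in both lines 141 did so, LFNG and EGR1 among them, and 1484 moved the same way. Groups simulated from the control means gave a covariance of 0.031, beside 0.105 observed, where genes that follow the APT1 level would lower it. They gave 0.1 genes called in both, a count that decides nothing, since no gene was changed in them. The observed correlation of 0.41 and the 66.7% of equal signs were not above the simulated 0.53 and 67.1%. The test covers only opposite responses to the APT1 level and cannot judge genes that move the same way when it is lowered or raised. The covariance alone argues against such opposite responses, and against noise in the shared control libraries, as the whole cause of the shared changes. How much of the overlap in calls that noise adds cannot be told from these simulations. A difference common to the 3 control libraries stays open and was not tested. Shifted chromosomes might also make the lines alike, but after the neighbouring-gene correction the covariance was still 0.094, which argues against them as the whole cause.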
